A study of Homo sapiens with 4 samples.

How the data were processed

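The series holds 4 Agilent two-colour whole human genome 60-mer arrays of HBL-1 lymphoma cells, 1 each for 6, 12, 24 and 48 h with 50 µM Z-VRPR-FMK or DMSO. Per the labels, RNA of the inhibitor-treated cells carried Cy5 and RNA of the time-matched DMSO cells carried Cy3 on every array. Arrays were grouped by hours with the inhibitor as the labels give them, and no label was missing.

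The deposited scanner output gives the mean signal and the local background of each spot and channel as intensity values, which the authors extracted with Feature Extraction 10.5.1.1 before any normalization. The same deposited output also holds Agilent's processed intensities, from which background was subtracted and which were dye-normalized, and per the file headers a log10 ratio of processed Cy5 over Cy3. The deposited series matrix holds log2 ratios of Cy5 over Cy3. They were checked against the deposited scanner log10 ratios divided by the log10 of 2 and differed by at most 5.0e-10, so that they carried Agilent's background and dye correction and no further centring. The matrix left 17850, 17819, 17721 and 16886 gene spots blank at 6, 12, 24 and 48 h.

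Each array had 45015 spots, of which 43376 carried gene probes. Spots that the scanner software marked as non-uniform, as population deviants or as lying in a non-uniform local background were set to missing, which took 261, 236, 172 and 230 spots. The removal of spots with a non-uniform local background before the background fit was decided after the data had been seen, because the background fit of the 48 h array failed. That array had 38 such spots, and 19 spots beside a bright streak had a local background over 100. With every spot in the fit the fitted background SD of the 48 h array was 2029 in 1 channel and 337 in the other. With all flagged spots left out it was 0.838 and 1.75. The removal departs from the plan as written, which kept every spot in the background fit and gave 0 genes on average and 0 for time in limma (4222 and 1405 at an unadjusted p under 0.05). Results of the plan as written are given as an alternative. Signals were background-corrected with normexp (offset 50) and normalized by loess within each array (4 iterations, control spots with weight 0) in limma 3.58.1 under R 4.3.3. A probe was kept when it was well above background in at least 1 channel on at least 3 of 4 arrays, which left 26175 of 41000 probes. Log2 ratios were averaged over spots of a probe and then over probes of a gene, which gave 19054 genes or transcripts, 19034 of them measured on all arrays and 5219 with more than 1 probe. Probes were named from the deposited accession or symbol through RefSeq names, and 5961 names were accessions or probe names only, which were counted and not named. Spike-in log ratios followed their nominal ratios with slopes of 0.945, 0.949, 0.936 and 0.924, and replicate spots of a probe had an SD of 0.058, 0.054, 0.051 and 0.053 log2 units. The number of arrays limits the precision.

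With 1 array per time, no single time was tested. The average log2 ratio over the 4 arrays was tested against 0, and the slope on log2 hours was tested in a second fit, both with limma lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05. The first of these treats the times as replicates, and its error includes any drift with time. Counts of genes at least 2-fold apart at each time, and of genes at least 1.5-fold apart in 1 direction at all 4 times, carry no test. A set of 27 gene lists was tested with limma camera (preset correlation 0.01, at least 5 measured members, adjusted over the lists), with camera's estimated correlation and limma fry beside it. With an estimated correlation camera takes the few residual degrees of freedom of 4 arrays, so its power is low whatever the correlation. The list of transcripts that MALT1 substrates destabilise had an estimated correlation of 0.0070 on average, below the preset one. Its camera adjusted p still went from 7.98e-06 to 0.431. A call lost in this form therefore does not show that correlation between genes gave the call. Apart from the spots left out and the alternative on GC content, the lists, the tests of genes and lists above, the alternatives and the rule for named genes were fixed before the data were examined. Some tests of other explanations were chosen after the results were seen and are marked where they are given. The rule names NFKBIZ, MALT1, NFKBIA and TNFAIP3 whatever their values, and the 12 highest and 12 lowest averages that passed with 1 sign at all times. It also names the up to 10 highest and 10 lowest slopes that passed, the 5 highest and 5 lowest log2 ratios per time, and up to 4 members per list with the largest average and the largest slope. Some genes that met this rule are not reported here.

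Procedures were tested on simulated data of the same size. An average log2 change of 1 was recovered in 87% of simulated genes and of 0.5 in 53%, and a slope of 1 in 77% and of 0.5 in 47%. The simulated noise came from the residuals of the fit with the slope on log2 hours. It was independent between genes and held no drift with time. The shares for the average therefore apply to a quieter setting than the real test, whose error includes drift. At the level of spots, a true log2 ratio of 1 was measured as 0.59 among the dimmest, 0.85 in the middle and 0.99 among the brightest, so that ratios of dim genes were pulled toward 0.

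Channel levels were compared after each array's channels were scaled to 1 distribution of brightness. Random lists matched for brightness were drawn 10000 times. The alternatives were no background correction, offset 10, Agilent's processed signals, median centring, scaling between arrays, other filters on dim probes, the brightest probe per gene, saturated spots set to missing, the deposited matrix values, each array left out, other priors, covariates and codings of time, the other set tests and a 1.5-fold threshold. Every spot in the background fit, the plan as written, became an alternative after the data were seen, and removal of the trend on probe GC content (loess, span 0.3) was added then. Data tables were handled with the R package data.table (version 1.17.8) and figures were drawn with matplotlib 3.10.9.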

Results

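Gene expression was measured in HBL-1, a human cell line of activated B cell-like (ABC) diffuse large B cell lymphoma. The cells received 50 µM Z-VRPR-FMK, a peptide inhibitor of the MALT1 protease, or DMSO for 6, 12, 24 or 48 h. RNA of the inhibitor-treated cells carried Cy5 and RNA of the DMSO-treated cells of the same time carried Cy3, and both were hybridised to 1 Agilent array per time. No time had a replicate array, and no array had the dyes exchanged, so a constant dye effect of a probe could not be separated from an average difference. Of 43376 gene spots per array, 58.3%, 58.9%, 61.5% and 64.0% were well above background in Cy3 at 6, 12, 24 and 48 h, and 62.7%, 67.2%, 65.2% and 66.6% in Cy5. No spot was saturated, and the number of arrays limits the precision of every value. After filtering, 19054 genes or transcripts remained, 13093 of them with a gene symbol. Across genes, which are not independent replicates, the log2 ratios of the 6 pairs of times correlated with r from 0.24 (6 and 48 h) to 0.70 (12 and 24 h).

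The title of the series names NFKBIZ and MALT1 inhibition, and the first comparison asked which genes differed from the DMSO control on average over the 4 times. NFKBIZ, which encodes the atypical IkB protein IkB-zeta, had an average log2 ratio of -1.004 (SE 0.065, n = 4 arrays, limma adjusted p = 0.0138). Its log2 ratios were -0.90, -0.97, -1.03 and -1.11 at 6, 12, 24 and 48 h, from 1 probe on chromosome 3 between 103061594 and 103061653 (human build hg18). TNFAIP3 on chromosome 6, which encodes A20, a brake on NF-kB signalling, fell by 0.58 (SE 0.11, 2 probes, limma adjusted p = 0.0445) and was lower at 4 of 4 times. NFKBIA, which encodes IkB-alpha, had log2 ratios of -0.19, -0.55, -0.71 and -1.32 from 1 probe on chromosome 14 between 34940539 and 34940598, and its average of -0.69 (SE 0.17) did not pass (limma adjusted p = 0.0642). MALT1 itself, on chromosome 18, had log2 ratios of 0.36, 0.12, 0.22 and 0.32 from 3 probes, and its average of 0.25 (SE 0.068) did not pass either (limma adjusted p = 0.0784). Its probes differed in sign at 12 h, where 1 lay at -0.13, and at 24 h, where another lay at -0.014. All other values of its probes were above 0. The call of TNFAIP3 ended without the 6, 12 or 24 h array (limma adjusted p = 0.0532, 0.145 and 0.232) and that of NFKBIZ without the 12 or 24 h array (limma adjusted p = 0.124 and 0.190). NFKBIA passed without the 48 h array (limma adjusted p = 0.0468). The adjusted p over all alternatives ran from 0.0057 to 0.232 for TNFAIP3, from 0.0020 to 0.190 for NFKBIZ, from 0.0057 to 0.847 for NFKBIA and from 0.0019 to 0.287 for MALT1.

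**Figure D1:**
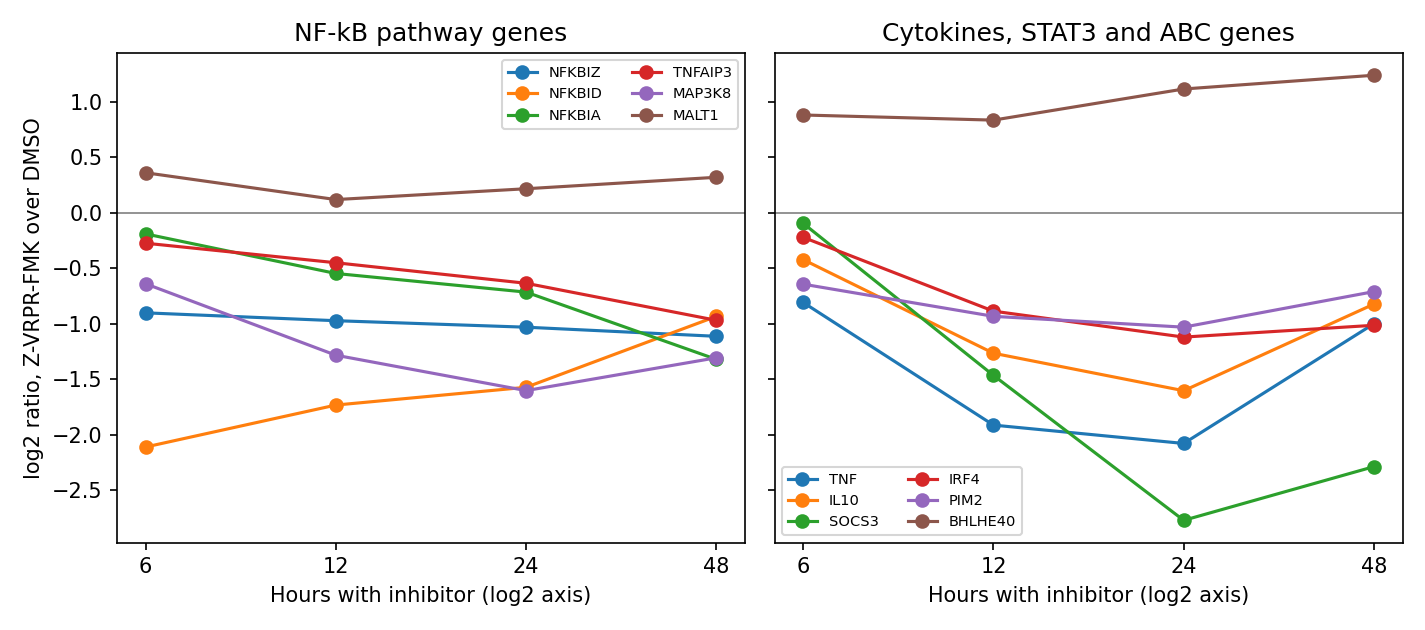
Log2 ratio of inhibitor over DMSO against hours with inhibitor (log2 axis), 1 array per time, for 6 NF-kB pathway genes (left) and 6 cytokine, STAT3 and ABC lymphoma genes (right). Each point is 1 array. NFKBIZ stayed between -0.90 and -1.11, and NFKBID went from -2.11 at 6 h to -0.93 at 48 h. BHLHE40 and MALT1, the latter as the average of its probes, were above 0 at all 4 times.

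Among the genes that passed with the largest falls on average were regulators and products of NF-kB signalling in B cells. NFKBID, which encodes the atypical IkB protein IkB-NS, had an average log2 ratio of -1.59. The cytokine gene TNF followed at -1.45, MAP3K8, a kinase upstream of ERK, at -1.21, the cytokine gene IL10 at -1.03 and the receptor gene CD40 at -0.89. The other genes among the 12 with the largest falls were TMPRSS6 (-1.22), RASSF4 (-1.15), NFKBIZ, MARCKS (-0.98), the histone methyltransferase gene SUV39H1 (-0.94), CFL1 (-0.92) and POU2F2 (-0.91), which encodes the B cell factor OCT2. Among genes that passed, the 12 with the largest rises were ADM (1.07), the transcriptional repressor gene BHLHE40 (1.02), METRNL (1.01), RASGRP2 (0.95), FAM117A (0.87), NDRG4 (0.85), GPSM1 (0.84), SAT2 (0.83), LDAF1 (0.81), EEIG1 (0.77), PRSS36 (0.77) and the ferritin gene FTL (0.77). The SE of these averages lay between 0.065 and 0.23 and their limma adjusted p between 0.0138 and 0.0476. Over all 19054 genes tested, 767 passed, 366 higher and 401 lower, with a median size of 0.45.

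The number of genes called on average rested on single arrays and on the background and dye correction. Without the 12 h or the 24 h array none passed in limma (smallest adjusted p = 0.124 and 0.190), although 3836 and 2924 genes had an unadjusted p under 0.05. Without the 6 h array 332 genes passed and without the 48 h array 1152. The genes FAM117A, FTL, GPSM1 and LDAF1 did not pass without the 6 h array (limma adjusted p from 0.0502 to 0.0601), nor did RASSF4 (0.0591) and SAT2 (0.0551) without the 48 h array. The plan as written kept every spot in the background fit, including 19 beside a bright streak on the 48 h array that were left out after the data had been seen. With every spot in the fit none passed (smallest limma adjusted p = 0.0679), although 4222 genes had an unadjusted p under 0.05. Centring each array on its median in place of loess moved the median of all genes to 0.25 and gave 8571 genes higher and 385 lower. Agilent's own processed signals gave 566 higher and 400 lower, a normexp offset of 10 gave 1255 calls, and log2 hours as a covariate gave 2624.

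The gene lists, each fixed by its members' known roles, moved down in NF-kB signalling. Of 19 measured NF-kB subunits, IkB proteins and feedback regulators, 6 fell, none rose and 13 did not pass (15 fell adjusted over the list alone). NFKBID, NFKBIZ and NFKB2 (-0.71) fell, the list median was -0.43, and camera gave adjusted p = 6.93e-10 (adjusted p = 0.494 with an estimated correlation). Of 38 textbook NF-kB targets, 8 fell, among them MAP3K8 and MARCKS, none rose and 30 did not pass, among them TNFAIP2 (-1.07) and EBI3 (-0.98). That list's median was -0.27 (20 fell and 3 rose adjusted over the list alone; camera adjusted p = 3.89e-06; adjusted p = 0.494 with an estimated correlation). Of 12 transcripts that the MALT1 substrates Regnase-1 and Roquin destabilise, 5 fell, among them NFKBID, TNF, NFKBIZ and IRF4 (-0.81), and 7 did not pass (8 fell and 1 rose adjusted over the list alone). Its median was -0.42 (camera adjusted p = 7.98e-06; adjusted p = 0.431 with an estimated correlation), and it was the only list of 27 that passed in fry (adjusted p = 0.0130). Counted over all 20 listed members, measured or not, it shares 5 with the NF-kB regulators and 4 with the NF-kB targets. It also shares 4 with the cytokines and chemokines, TNF among them. Of 18 cytokines and chemokines, 4 fell, among them TNF, IL10 and LTA (-0.65), and 14 did not pass (6 fell adjusted over the list alone). LTA did not pass without the 48 h array (limma adjusted p = 0.0580). Their median was -0.24 (camera adjusted p = 3.22e-04; adjusted p = 0.567 with an estimated correlation).

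The next lists hold signalling and identity genes of ABC lymphoma. Of 22 JAK-STAT3 genes, 3 fell (IL10, the kinase gene PIM2 at -0.83 and STAT5A at -0.66), and 19 did not pass, among them the feedback inhibitor SOCS3 (-1.65, limma adjusted p = 0.0629). The JAK-STAT3 median was -0.20 (9 fell adjusted over the list alone; camera adjusted p = 2.98e-05; adjusted p = 0.494 with an estimated correlation). Of 31 genes that mark ABC against germinal centre lymphoma, 6 fell, among them IRF4, PIM2 and BMF (-0.75), 1 rose and 24 did not pass, with a median of -0.22 that turned to 0.06 above all genes under median centring. The ABC list gave camera adjusted p = 0.0012 (adjusted p = 0.494 with an estimated correlation; 14 fell and 1 rose adjusted over the list alone). Of 22 germinal centre markers, NEK6 (0.63) and ITPKB (0.35) rose and 20 did not pass (4 rose and 1 fell adjusted over the list alone). The germinal centre list had a median of 0.13 and did not pass (camera adjusted p = 0.0576), but did without the 6 h array (camera adjusted p = 0.0452) and without the 24 h array (camera adjusted p = 0.0346). Of 29 genes of the routes from the B cell receptor and MYD88 to MALT1, RC3H1 (-0.40) and RBCK1 (-0.37) fell and 27 did not pass (8 fell and 3 rose adjusted over the list alone). The median of the list was -0.12 and turned to 0.021 above all genes under median centring, where RBCK1 turned to 0.014. That list gave camera adjusted p = 0.0137 (adjusted p = 0.494 with an estimated correlation) and did not pass without the 12 h array (camera adjusted p = 0.0535). Of 26 mature B cell genes, 7 fell, among them POU2F2, CD22 (-0.69) and EBF1 (-0.63), and 19 did not pass (7 fell and 1 rose adjusted over the list alone). Their median was -0.049 (camera adjusted p = 0.0459; adjusted p = 0.567 with an estimated correlation). It turned to 0.094 above all genes under median centring and to 0.013 without the 6 h array (camera adjusted p = 0.387), and the call also ended without the 12 h array (camera adjusted p = 0.0664). The B cell list passed in only 8 of 19 alternatives. Without the 6 h array BMF, NEK6, ITPKB, RC3H1 and RBCK1 did not pass alone (limma adjusted p = 0.0524, 0.0642, 0.0768, 0.0608 and 0.0637), nor did ITPKB without the 48 h array (limma adjusted p = 0.0523). The range of the adjusted p over all alternatives was 0.0088 to 0.494 for the germinal centre list, 0.0076 to 0.494 for the routes to MALT1 and 0.0025 to 0.567 for the B cell list.

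The G1/S, G2/M, MYC and ribosome, heat shock, interferon and ATF4 lists were lower on average, and the lysosome and MHC class II lists higher. In each of these lists at most 2 members passed alone: POLE2 (-0.49) of 30 G1/S genes, CENPA (-0.66) of 30 G2/M genes, PPAN (-0.62) of 26 MYC and ribosome genes, HSPH1 (-0.50) and HSP90AB1 (-0.34) of 21 heat shock genes, and 1 of 36 interferon-induced genes, which fell. The list medians were -0.28 for G1/S (camera adjusted p = 1.19e-05; adjusted p = 0.714 with an estimated correlation), -0.34 for interferon (camera adjusted p = 1.76e-06; adjusted p = 0.643 with an estimated correlation) and -0.22 for G2/M (camera adjusted p = 8.38e-04; adjusted p = 0.714 with an estimated correlation). Genes of the amino acid and integrated stress response, targets of ATF4, had a median of -0.25 over 28 members, none of which passed (camera adjusted p = 0.0012; adjusted p = 0.714 with an estimated correlation). The MYC and ribosome list had a median of -0.13 (camera adjusted p = 0.0029; adjusted p = 0.643 with an estimated correlation). Under median centring it turned to 0.19 above all genes, and the list passed in the upward direction. The heat shock list had a median of -0.12, which turned to 0.0057 above all genes under median centring, as did its genes HSP90AB1 (0.26) and HSPH1 (0.19); its camera adjusted p was 0.0015 (adjusted p = 0.494 with an estimated correlation). The lysosome list had a median of 0.23 over 25 members, none of which passed (camera adjusted p = 0.0029; adjusted p = 0.714 with an estimated correlation). The MHC class II list had a median of 0.18 over 17 members, none of which passed (camera adjusted p = 0.0284; adjusted p = 0.714 with an estimated correlation). Without the 48 h array the calls of G2/M (camera adjusted p = 0.978), ATF4 (0.657), MHC class II (0.708) and lysosome (0.127) ended, so that 12 lists passed in place of 16. Under median centring the calls of G1/S, G2/M, ATF4 and MHC class II ended. With every spot in the background fit the MHC class II call ended too (camera adjusted p = 0.0872), and it held in 13 of 19 alternatives. Without the 6 h array POLE2, CENPA and HSP90AB1 did not pass alone (limma adjusted p = 0.0642, 0.0518 and 0.0782). Taken above that of all genes, the G1/S median was -0.11 without the 48 h array and the heat shock median -0.085 without the 12 h array. The interferon median was -0.54 without the 6 h array and -0.18 without the 24 h array. These calls held without those arrays. Over all alternatives the adjusted p ran from 4.27e-06 to 0.978 for G2/M, from 3.72e-05 to 0.714 for ATF4, from 3.14e-04 to 0.714 for MHC class II and from 6.25e-07 to 0.714 for lysosome.

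The other 10 lists did not pass on average, and in some of them single genes did. The unfolded protein response, NRF2 and myeloid lists each passed in 1 alternative (lowest camera adjusted p = 0.0183, 0.0353 and 0.0300). HMOX1 (0.55) and FTL rose among 19 NRF2 targets, whose median was -0.0018 and whose mean was 0.098 (camera upward, adjusted p = 0.529). MSMO1 (0.76) rose among 22 cholesterol synthesis genes (median 0.14, camera adjusted p = 0.257). That list passed without the 6 h array (camera adjusted p = 0.0452; 0.0027 to 0.978 over all alternatives). ADM rose while ANKRD37 (-0.61) fell among 25 hypoxia and glycolysis genes (median -0.029, camera adjusted p = 0.347). HYOU1 (-0.52) fell among 20 genes of the unfolded protein response (median 0.048, camera adjusted p = 0.751). HYOU1, FTL and BMF did not pass without the 6 h array (limma adjusted p = 0.0689, 0.0587 and 0.0524). Of 28 p53 targets and apoptosis genes, BMF fell and 1 gene rose (median 0.0081, camera adjusted p = 0.735). None of the members passed among plasma cell genes (median 0.050, camera adjusted p = 0.611) or AP-1 genes (median -0.013, camera adjusted p = 0.904). None did among markers of other cell types either: 8 T and NK cell markers (median 0.12, camera adjusted p = 0.529), 6 myeloid markers (median 0.026, camera adjusted p = 0.611) and 9 stromal and epithelial markers (median -0.019, mean 0.057, camera downward, adjusted p = 0.887).

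**Figure D2:**
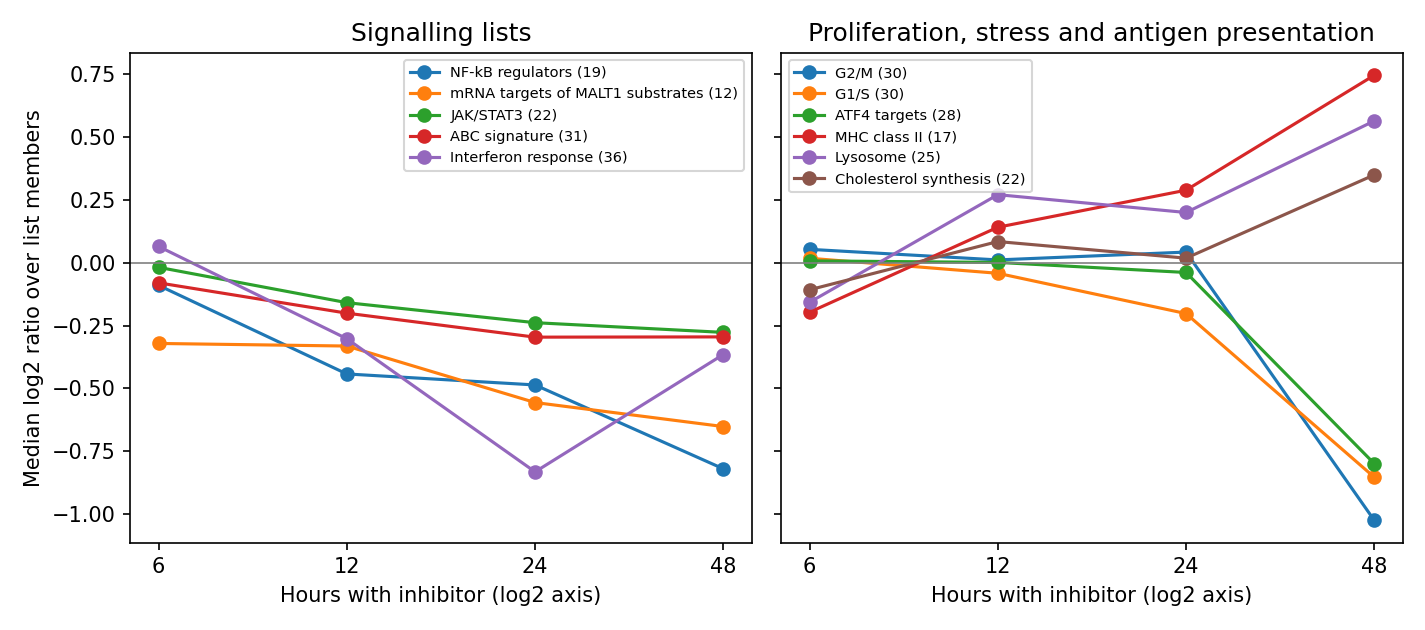
Median log2 ratio of inhibitor over DMSO over the members of each list (number of measured members in brackets) against hours with inhibitor (log2 axis), 1 array per time. Signalling lists are on the left, where the NF-kB regulators reached -0.82 at 48 h, and proliferation, stress and antigen presentation lists on the right, where G2/M, G1/S and ATF4 targets lay at -1.03, -0.85 and -0.80 at 48 h.

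The second comparison asked which genes drifted away from the DMSO control with time, as the slope of the log2 ratio on log2 hours, in which a constant dye effect cancels. Slopes rose for NSG1 (0.81 per doubling of time), the cholesterol exporter gene ABCG1 (0.78), RHOBTB2 (0.73) and IFI30 (0.71), a lysosomal thiol reductase of antigen processing. ABCG1 went from 0.16 at 6 h to 2.44 at 48 h and IFI30 from -0.016 to 2.17. Slopes fell for the receptor kinase gene EPHB1 (-0.95), GPRC5B (-0.77), IZUMO4 (-0.76), the metalloprotease gene ADAM8 (-0.76) and the interferon-induced gene IFIT2 (-0.53). GPRC5B was close to background, with Cy3 not well above it at 6 h, where the log2 ratio was 0.085. Its Cy5 was not well above background at 24 h, where it was at least 2.75-fold lower. The slope SE of these 9 genes lay between 0.053 and 0.094 and their limma adjusted p between 0.0440 and 0.0447. Over 19053 genes, 13 passed (7 rising, 6 falling, 10 with a symbol), 2536 had an unadjusted p under 0.05, and none of the 13 was among the genes called on average.

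The calls for time stood close to the threshold, and the plan as written, with every spot in the background fit, gave none. In limma 16 genes passed without the 6 h array, none without the 12 h array (smallest adjusted p = 0.111, 2132 genes at an unadjusted p under 0.05), 503 without the 24 h array and 37 without the 48 h array. Only EPHB1, ADAM8, GPRC5B and IZUMO4 of the named genes passed without the 6 h array, and IFIT2 and IZUMO4 did not pass without the 48 h array (limma adjusted p = 0.0534 and 0.0536). None passed with Agilent's processed signals, the deposited ratios, scaling between arrays, no filter on dim probes, every spot in the background fit or a contrast of the later with the earlier times (smallest limma adjusted p = 0.160, 0.0620, 0.0740, 0.0686, 0.175 and 0.661), although 2241, 2185, 2245, 3434, 1405 and 1058 genes had an unadjusted p under 0.05.

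The G1/S, G2/M and ATF4 target lists fell with time, mostly at 48 h, where their medians with every spot in the background fit were -0.41, -0.52 and -0.40. No member of these lists passed for time over all genes. The 30 G1/S genes had list medians of 0.018, -0.042, -0.20 and -0.85 at 6, 12, 24 and 48 h, and all 30 slopes were negative, with CDT1 at -0.49 and MCM10 at -0.44 (23 fell adjusted over the list alone; camera adjusted p = 1.53e-17; adjusted p = 0.492 with an estimated correlation). The 30 G2/M genes had medians of 0.053, 0.011, 0.043 and -1.03, with all 30 slopes negative (none fell adjusted over the list alone; camera adjusted p = 2.29e-13; adjusted p = 0.492 with an estimated correlation). The 28 ATF4 targets had medians of 0.0075, 0.0014, -0.039 and -0.80, with all 28 slopes negative and 48 h values of -1.64 for ATF3 and -1.62 for PHGDH (6 fell adjusted over the list alone; camera adjusted p = 1.005e-11; adjusted p = 0.492 with an estimated correlation). Without the 48 h array the G2/M slope was -0.0044 above that of all genes, with an upward test (camera adjusted p = 0.752), the ATF4 slope was -0.017 (camera adjusted p = 0.657) and the G1/S slope was -0.098 (camera adjusted p = 5.01e-05). Without the 6 h array the G2/M and ATF4 slopes were -0.47 and -0.38. Over all alternatives the adjusted p ran from 4.20e-28 to 0.752 for G2/M and from 9.22e-21 to 0.657 for ATF4.

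Levels within each dye channel, scaled to 1 brightness distribution over the arrays, were compared between times. Each level comes from 1 array, so a change in a culture cannot be told apart from a difference between arrays. The levels were computed only with flagged spots left out of the background fit, and not under the plan as written. Between 24 and 48 h the median ATF4 target was 1.32 higher in the DMSO culture (27 of 28 members up) and 0.43 higher in the inhibitor culture. The median G2/M gene was 0.062 higher in the DMSO culture and -0.90 in the inhibitor culture, where 30 of 30 members were lower. The median G1/S gene lay at -0.53 in the DMSO culture and -1.08 in the inhibitor culture, values with no test. The median interferon-induced gene between 6 and 24 h was 0.49 higher in the DMSO culture (34 of 36 members up) and -0.42 in the inhibitor culture (30 of 36 members down). Between 6 and 48 h the median MHC class II gene was -0.38 in the DMSO culture and 0.58 in the inhibitor culture.

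**Figure D3:**
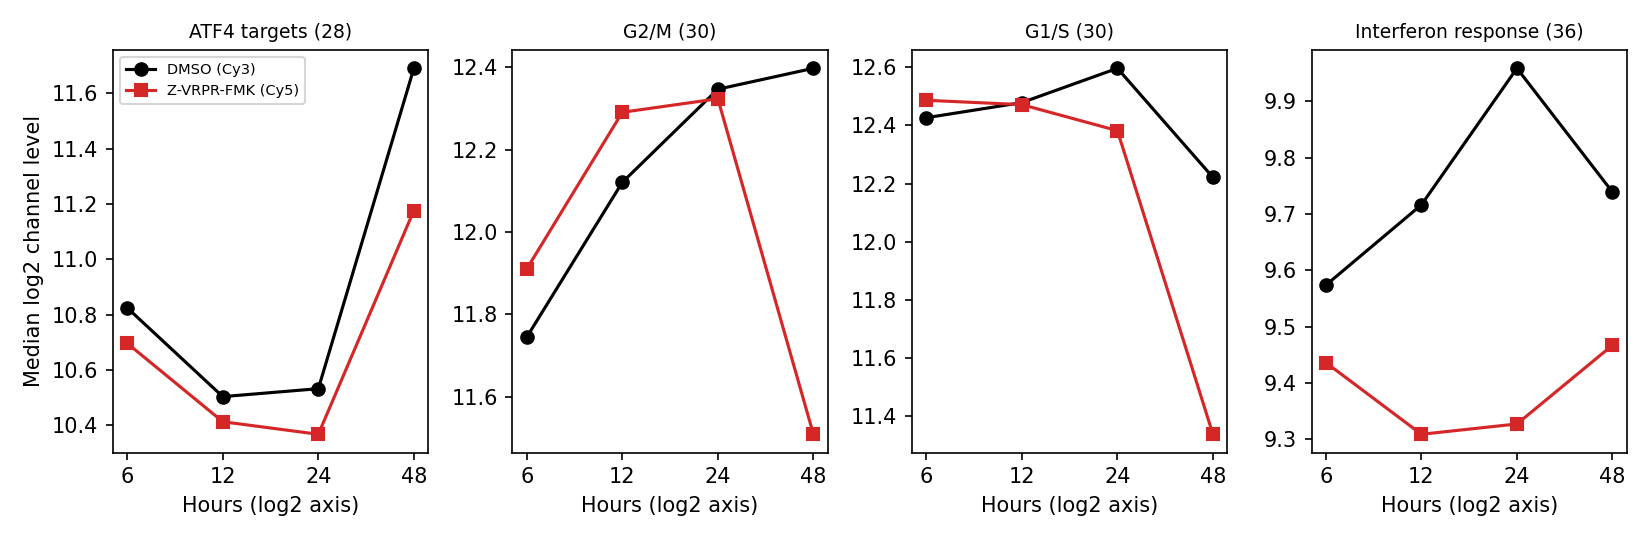
Median log2 channel level over the members of 4 lists (number of members in brackets) against hours (log2 axis), DMSO culture in Cy3 (black circles) and Z-VRPR-FMK culture in Cy5 (red squares), 1 array per time. Between 24 and 48 h the ATF4 targets were higher by 1.32 in the DMSO culture for the median member, and the G2/M genes lay at -0.90 in the inhibitor culture.

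NF-kB and interferon lists also fell with time. Among the members of the 5 lists in this paragraph, only IFIT2 passed for time over all genes. The NF-kB regulators had medians of -0.090, -0.44, -0.49 and -0.82 at 6, 12, 24 and 48 h, and 17 of 19 slopes were negative, with TRAF2 at -0.44 and BCL3 at -0.38 against NFKBID at 0.37 (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.42e-06; adjusted p = 0.492 with an estimated correlation). The NF-kB targets had medians of -0.059, -0.21, -0.33 and -0.36, with 27 of 38 slopes negative (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.39e-05; adjusted p = 0.492 with an estimated correlation). The interferon-induced genes had medians of 0.065, -0.30, -0.83 and -0.37, lowest at 24 h, where IFIT1 lay at -2.09 (1 fell adjusted over the list alone; camera adjusted p = 2.47e-05; adjusted p = 0.652 with an estimated correlation). The JAK-STAT3 genes had medians of -0.018, -0.16, -0.24 and -0.28 (none passed adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.492 with an estimated correlation). The cytokines and chemokines had medians of -0.053, -0.20, -0.42 and -0.31 (3 fell adjusted over the list alone; camera adjusted p = 0.0327; adjusted p = 0.652 with an estimated correlation). Without the 6 h array none of these 5 passed (camera adjusted p = 0.0681, 0.0754, 0.782, 0.328 and 0.937, the interferon and cytokine slopes turning to 0.0025 and 0.0054), and the cytokine list did not pass without the 24 h array either (camera adjusted p = 0.247). With every spot in the background fit the JAK-STAT3 and cytokine lists did not pass (camera adjusted p = 0.104 and 0.438), the cytokine list passed in 10 of 20 alternatives, and the 48 h medians of the NF-kB regulators, NF-kB targets, interferon-induced, JAK-STAT3 and cytokine genes were -0.19, -0.091, -0.026, -0.018 and -0.016. Without the 48 h array the slopes of the NF-kB regulators, interferon and cytokine lists were -0.20, -0.49 and -0.18. The alternatives gave a highest adjusted p of 0.492 for the NF-kB and JAK-STAT3 lists, 0.782 for interferon and 0.937 for cytokines, and the lowest was 1.10e-07, 1.34e-08, 1.61e-06, 5.59e-36 and 1.54e-07 for NF-kB regulators, NF-kB targets, JAK-STAT3, interferon and cytokines.

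Antigen presentation, lysosome, cholesterol, B cell and plasma cell lists rose with time. No member of these lists passed for time over all genes. The 17 MHC class II genes had medians of -0.20, 0.14, 0.29 and 0.75, all 17 slopes were positive, and HLA-DRA reached 1.43 at 48 h (13 rose adjusted over the list alone; camera adjusted p = 6.92e-14; adjusted p = 0.492 with an estimated correlation). The 25 lysosome genes had medians of -0.16, 0.27, 0.20 and 0.56, with 24 slopes positive and TPP1 at 1.14 at 48 h (12 rose adjusted over the list alone; camera adjusted p = 2.39e-11; adjusted p = 0.492 with an estimated correlation). The 22 cholesterol genes had medians of -0.11, 0.084, 0.018 and 0.35 (none passed adjusted over the list alone; camera adjusted p = 1.74e-04; adjusted p = 0.492 with an estimated correlation). The mature B cell genes had medians of -0.25, -0.032, -0.076 and 0.10, with MS4A1, the CD20 gene, at 1.11 and TNFRSF13C, the BAFF receptor gene, at 1.58 at 48 h (9 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0061; adjusted p = 0.492 with an estimated correlation). The plasma cell genes had medians of -0.0052, 0.14, 0.081 and 0.27, with JCHAIN at 1.54 at 48 h (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0074; adjusted p = 0.492 with an estimated correlation). The cholesterol list did not pass without the 48 h array (camera adjusted p = 0.204), and the B cell and plasma cell lists passed neither without the 6 h array (camera adjusted p = 0.0681 and 0.423) nor without the 48 h array (camera adjusted p = 0.0560 and 0.0706). Over all alternatives the adjusted p ran to 0.492 in each of these 5 lists, from 2.74e-05 for cholesterol, 9.14e-07 for B cell and 5.97e-04 for plasma cell genes. With every spot in the background fit the 48 h medians were 0.27 for MHC class II, below that at 24 h, 0.36 for lysosome, 0.32 for cholesterol, 0.056 for B cell and 0.17 for plasma cell genes. Of the 27 lists, 13 passed with all arrays and 7 without the 6 h array.

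The other 14 lists did not pass for time. Median slopes were -0.021 for the ABC list (camera adjusted p = 0.0609), 0.033 for the germinal centre list (camera adjusted p = 0.148), -0.072 for the targets of MALT1 substrates (camera adjusted p = 0.213), -0.023 for the routes to MALT1 (camera adjusted p = 0.706) and -0.050 for AP-1 (camera adjusted p = 0.282). They were 0.0041 for MYC and ribosome genes (camera adjusted p = 0.920), 0.063 for the unfolded protein response (camera adjusted p = 0.172), 0.021 for heat shock (camera adjusted p = 0.920), 0.0030 for NRF2 (camera adjusted p = 0.899) and -0.024 for hypoxia (camera adjusted p = 0.353). The p53 list had a median of -0.0053, a mean of 0.0097 and a downward test (camera adjusted p = 0.971). Markers of other cell types had median slopes of 0.0038 (T and NK, camera adjusted p = 0.525), -0.026 (myeloid, camera adjusted p = 0.762) and -0.0091 (stromal and epithelial, mean 0.078, upward test, camera adjusted p = 0.220). Single arrays changed 3 of these: without the 48 h array the ABC list (camera adjusted p = 0.0022), the MYC and ribosome list (-0.054, camera adjusted p = 0.0125) and the unfolded protein response (camera adjusted p = 7.74e-06) passed. The unfolded protein response also passed without the 12 h array (camera adjusted p = 0.0131) and, downward at -0.096, without the 6 h array (camera adjusted p = 0.0354). Over all alternatives the adjusted p ran from 0.0022 to 0.673 for the ABC list, from 0.0125 to 0.977 for MYC and ribosome genes and from 7.74e-06 to 0.842 for the unfolded protein response.

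Single times have no replicate and no test, and their lowest values were held by different genes. NFKBID was the lowest gene at 6 h (-2.11) and TNF at 12 h (-1.91), SOCS3 was lowest at 24 h (-2.77) and EPHB1 at 48 h (-2.86). With no filter on dim probes SOCS3 lay at -1.49 at 24 h. At 12 h the next lowest were NFKBID (-1.73), SOCS3 (-1.46), MAP3K8 (-1.28) and IL10 (-1.26), and at 24 h EPHB1 (-2.22), IFIT1 (-2.09), TNF (-2.08) and LRRC32 (-2.06). At 48 h ADAM8 (-2.62), SOCS3 (-2.29), GPRC5B (-2.14) and IZUMO4 (-2.10) followed, and at 6 h TM2D3 (-1.03), PRKCSH (-1.03), NOMO1 (-0.97) and ENPP4 (-0.95). The highest were CARHSP1 (1.85), PRPF19 (1.34), PFDN6 (1.04), H4C15 (1.03) and H4C6 (0.97) at 6 h, and NDRG4 (1.24), CORO6 (1.24), ADM (1.13), RHOBTB2 (1.08) and UAP1L1 (1.07) at 12 h. At 24 h they were CRYM (2.46), ABCG1 (1.98), NSG1 (1.96), RHOBTB2 (1.91) and the T cell kinase gene LCK (1.52), and at 48 h CRYM (3.76), MYADML2 (2.82), STRA8 (2.71), TMEM121B (2.57) and WNT3 (2.51). With every spot in the background fit 8 of the 10 values named for 48 h moved by over 1.5 times, EPHB1 to -0.49, SOCS3 to -0.38, GPRC5B to -0.14, IZUMO4 to -0.50, MYADML2 to 0.75, STRA8 to 0.45, TMEM121B to 0.63 and WNT3 to 0.66. Over all 4 times, 8 of the named values moved so under median centring and 3 with no filter on dim probes. The count was 2 each with Agilent's processed signals and the deposited values.

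At least 2-fold differences were found in 30 genes at 6 h (24 higher, 6 lower), 39 at 12 h (16 higher, 23 lower), 139 at 24 h (67 higher, 72 lower) and 369 at 48 h (170 higher, 199 lower), but only 82 at 48 h (49 higher, 33 lower) with every spot in the background fit. The SD over genes was 0.24, 0.23, 0.27 and 0.36. Median centring gave 173 higher and 1 lower at 6 h, 615 and 4 at 12 h, 196 and 36 at 24 h, and 1051 and 39 at 48 h. Agilent's processed signals gave 394 higher and 119 lower, 555 and 129, 451 and 208, and 565 and 455.

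Differences of at least 1.5-fold in 1 direction at all 4 times were found in 33 genes, 14 higher and 19 lower, among them NFKBIZ, NFKBID and PIM2 lower and BHLHE40 and GPSM1 higher. All 33 were among the genes called on average in limma. The count was 129, 45, 34 and 92 without the 6, 12, 24 and 48 h array. Fewer times had to meet the limit in each case, and the size of the rise depended on which array was left out. With every spot in the background fit there were 3 genes, and a normexp offset of 10 gave 64. Median centring gave 565 higher and 1 lower, and Agilent's processed signals gave 181 higher and 61 lower.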

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

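The tests of a constant dye bias, of the removal of the GC trend, of the processing of the 48 h array and of a fault of the 24 h array were chosen only after the result was seen, and the other tests in this part were planned.

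Genes and lists whose effect of the inhibitor differed between times, by the tested slope on log2 hours, are collected here. They were the genes NSG1 (0.81 per doubling of time), ABCG1 (0.78), RHOBTB2 (0.73), IFI30 (0.71), IFIT2 (-0.53), ADAM8 (-0.76), IZUMO4 (-0.76), GPRC5B (-0.77) and EPHB1 (-0.95). The lists that rose with time were MHC class II (0.29), lysosome (0.21), plasma cell (0.18), cholesterol (0.11) and mature B cell genes (0.096). The lists that fell were JAK-STAT3 (-0.085), cytokines (-0.086), NF-kB targets (-0.12), NF-kB regulators (-0.12), interferon (-0.15), ATF4 targets (-0.22), G2/M (-0.29) and G1/S (-0.29). None of these 13 lists passed with an estimated correlation. The 12 orders of the arrays that differ from one another are too few for a share under 0.05. The real order gave 13 genes and the highest other 0, and 1 order gave as many. For lists the real order gave 13 and the highest other, with 24 and 48 h exchanged, also gave 13, so that 2 orders gave as many. For the average, the 8 ways to turn the dye sign of arrays are too few for a share under 0.05: the real signs gave 767 genes (1 way as large, highest other 0) and 16 lists (2 ways as large, highest other 19 with the 12, 24 and 48 h signs turned, which sets 6 h against the later times).

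The genes called on average were weighed against dye bias, because the inhibitor carried Cy5 on every array. After removal of the trend on probe GC content 91.5% of the genes called were still called, and Spearman's rho between GC and the average was -0.027 across genes, which argues against a bias that follows GC as the whole cause. Any other constant dye bias cannot be told apart from an average effect gene by gene, since the ratio of the median size at 6 h to that at 48 h was 0.926 among called genes but the test itself prefers steady genes. The median of the NF-kB regulator list differed by -0.73 between 6 and 48 h, past the bound set for a constant bias. The SD of random lists was 0.093 and the median change of its members -0.45. With every spot in the background fit the list median was -0.090 at 6 h and -0.19 at 48 h, within that bound. That fit shrank the ratios of the 48 h array, so its 48 h value cannot show that the list stayed constant. That setting left the list medians at 6, 12 and 24 h almost unchanged, so the values of -0.44 at 12 h and -0.49 at 24 h gain no support from it. They lay below the 6 h median, a difference that a constant bias alone does not give. This difference rests on the 6 h array, without which the list's slope was -0.065 and did not pass (camera adjusted p = 0.0681). Because the contrast with 6 h rests on 1 array, a constant bias as a cause of the list's lower values at 12, 24 and 48 h stays open.

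The ATF4, G2/M and G1/S lists were lower at 48 h than at 24 h, and this was weighed against the control culture and the processing of the 48 h array. Less the median of equally bright genes, the value nearest 0 over the processing alternatives was -0.47 for ATF4 (main -0.77), -0.71 for G2/M (main -1.002) and -0.55 for G1/S (main -0.87), which argues against background correction or normalization as the whole cause. The planned form of this test, without the brightness match, was replaced after it was seen: under median centring the 48 h medians went from -0.80 to -0.28 for ATF4, from -1.03 to -0.50 for G2/M and from -0.85 to -0.42 for G1/S, so that a part of the processing in their size stays open. In the DMSO culture the median ATF4 target was 1.32 higher at 48 h than at 24 h, so that a change in the control culture is a candidate explanation of the ATF4 values. Channel levels were computed only with flagged spots left out of the background fit. In that setting the median G2/M gene was 0.062 higher and the median G1/S gene -0.53 in the DMSO culture. These values argue against a change in the control as the cause of the 2 falls in that setting. A slowing of the cell cycle under the inhibitor may explain the falls, as a hypothesis that rests on 1 array of 1 time.

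The interferon-induced genes were lowest at 24 h, and this was weighed against the control culture and a fault of that array. At 12 h their median was already -0.30, with 0% of random lists of like brightness lower, which argues against a fault of the 24 h array alone, while the 48 h median of -0.37 went to -0.026 with every spot in the background fit and is not counted. In the DMSO culture the median member was 0.49 higher at 24 h than at 6 h, which is 49.0% of the fall of the ratio, and at 48 h it was -0.40 against 24 h, which is 70.4% of the ratio's return of 0.57. The first share lay between the bounds set for the test and the second, which goes with a change in the control culture, had none, so that this explanation stays open. No biological explanation of the rest was tested.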

How the results depend on the processing

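The plan as written kept every spot in the background fit, and leaving spots out of it was decided after the data were seen, so that the planned setting is given here as an alternative. The alternative with the GC trend removed was also chosen after the data were seen, and all others were planned. No paired analysis was possible because each time had a single array, and slide or scan date as a block was not run because there was 1 slide and 1 scan date. A share of 58.3% to 67.2% of gene spots per channel was well above background, which limits the ratios of dim genes, and setting saturated spots to missing moved nothing, as none was saturated. List values here are list medians above the median of all genes.

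Leaving out each array gave 0 to 1152 genes on average, 0 to 503 for time, 34 to 129 at least 1.5-fold in 1 direction at all remaining times, 12 to 17 lists on average and 7 to 14 for time. Where a list turned, its range without each array was -0.13 to 0.013 for B cell and -0.34 to 0.0016 for G2/M on average, and for time -0.18 to 0.0054 for cytokines, -0.49 to 0.0025 for interferon, -0.47 to -0.0044 for G2/M (upward test), -0.054 to 0.086 for MYC and ribosome and -0.096 to 0.20 for the unfolded protein response. Fewer arrays lower the power, and beyond that the cause was not tested.

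Median centring gave 8956 genes on average and 144 for time, 174, 619, 232 and 1090 genes at least 2-fold apart at 6, 12, 24 and 48 h, and 566 at least 1.5-fold at all times. It turned the average of HSP90AB1 to 0.26, HSPH1 to 0.19 and RBCK1 to 0.014, and that of the lists for the routes to MALT1 to 0.021, ABC to 0.062, B cell to 0.094, MYC and ribosome to 0.19, heat shock to 0.0057, NRF2 to 0.21 and myeloid markers to -0.28. The average calls of G1/S, G2/M, ATF4 and MHC class II ended. With median centring 5 lists passed higher and 7 lower, in place of 2 and 14. The median of all genes then lay at 0.25, because the trend of the ratio on brightness stays in without loess.

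Agilent's processed signals gave 0 genes for time in limma (2241 at an unadjusted p under 0.05), 513, 684, 659 and 1020 genes at least 2-fold apart and 242 at least 1.5-fold at all times. The deposited matrix gave 0 for time in limma (2185 unadjusted), 157, 188, 336 and 735, and 85. An offset of 10 gave 1255 on average, 30 for time, 86, 96 and 238 at 6, 12 and 24 h, and 64, as a smaller offset shrinks dim ratios less. With every spot in the background fit, the plan as written, limma gave 0 on average (4222 unadjusted) and 0 for time (1405 unadjusted), with 82 genes at least 2-fold apart at 48 h and 3 at least 1.5-fold at all times, because that array's ratios shrank. For time limma gave 0 with scaling between arrays (2245 unadjusted), 0 with no filter on dim probes (3434 unadjusted), 0 for later against earlier times (1058 unadjusted), 24 with no background correction, 24 with a trend and robust prior, 20 with the GC trend removed and 158 with time in hours. With log2 hours as a covariate 2624 genes passed on average. The cause of these was not tested. The 1.5-fold threshold gave 459, 375, 725 and 1681 genes by construction. An estimated correlation gave 0 lists on average and 0 for time in camera, where the preset one gave 17 and 14 at an unadjusted p under 0.05, and fry gave 1 and 0. The estimated form also leaves camera few residual degrees of freedom, so these counts cannot tell correlation between genes from low power.

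Over all alternatives, 446 of 511 list values on average were counted as kept, 48 lost the call, 8 gained it and 9 turned. For time the counts were 480 of 538, 46, 7 and 5. Of the 48 genes followed for their average, 664 of 864 values were counted as kept, 191 lost the call, 6 gained it and 3 turned. Of the 10 followed for time 107 of 188 were counted as kept and 81 lost the call. Values at single times moved by over 1.5 times in 23 of 478 cases. A list or gene value counted as kept stayed on its side of the threshold and, where either setting passed, kept its direction. Among those kept are 54 values that passed no threshold in either setting and changed sign. Lists that never passed also count as kept, as do all values with saturated spots missing, where nothing could move.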

Other observations

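This part reports values and no test chosen after they were seen. Several lists lay on opposite sides of 0 at 6 h and later. The unfolded protein response had medians of -0.27, 0.18, 0.13 and -0.015 at 6, 12, 24 and 48 h, and its members included the chaperone gene HSPA5 (-0.28, 0.49, 0.45 and 0.51) and PDIA3 (-0.53, 0.56, 0.37 and 0.28), which encodes a disulfide isomerase. The plasma cell receptor gene TNFRSF17 had log2 ratios of -0.68, 0.10, 0.35 and 0.34. In the lysosome list, CTSA (-0.68, 0.077, 0.19 and 0.80), PSAP (-0.36, 0.042, 0.20 and 1.07) and TPP1 (-0.35, 0.19, 0.38 and 1.14) were also below 0 at 6 h and highest at 48 h, although the probes of CTSA differed in sign. None of these genes passed for time over all genes.

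Immediate early genes of the EGR family, which follow antigen receptor and ERK signalling, had higher ratios at 48 h than at 6 h. EGR2 had log2 ratios of -0.14, 0.38, 0.76 and 1.48 (limma adjusted p for the slope = 0.0587), EGR1 of -0.070, 0.58, 0.83 and 0.82, and EGR3 of -0.18, -0.086, 0.25 and 0.70. None of these genes passed for time over all genes, and EGR3 was not well above background in Cy3 at 12 h. Most of the AP-1 list that holds them went the other way, with 16 of 23 slopes below 0. In the same list BATF, an AP-1 factor of activated lymphocytes, was lower at -0.0014, -0.57, -0.91 and -0.85, and the AP-1 list as a whole did not pass. The growth arrest gene BTG2 had log2 ratios of -0.50, -0.27, 0.52 and 0.76, and the adhesion gene PECAM1 of 0.10, 0.59, 1.12 and 1.29.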
